A study of Mus musculus with 35 samples.

How the data were processed

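RNA of brain hemispheres from male beta2 adrenergic receptor knockout mice and wild type FVB mice was measured on Affymetrix mouse genome arrays. Per the labels there were 7 MCAO and 3 sham arrays of each genotype, taken 24 h after surgery, and 8 wild type and 7 knockout naive arrays. The values the authors deposited are log2 signals after RMA per the submitters' processing notes, with the RMA version not given. The naive arrays were normalized apart from the surgery arrays per the labels, so the sets were never compared in value. The labels give each array a replicate number and do not say whether the arrays are separate animals; p-values measure the spread between arrays.

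The table held 45101 probe sets, of which 64 were controls, 34958 had 1 gene symbol, 932 had several and 9211 had no gene listed. Of the probe sets with 1 symbol 34754 matched the reference by Entrez ID. Each of 18194 genes was represented by the probe set with the highest mean over the arrays of the fit; 9182 genes had 1 probe set and 9012 several. The targeted receptor gene is not reported here.

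Groups were taken from the labels. In R 4.3.3 with limma 3.58.1, lmFit, contrasts.fit and eBayes were fitted once to the 20 surgery arrays (MCAO against sham in each genotype, the difference of these changes, and knockout against wild type after each surgery) and once to the naive arrays (knockout against wild type). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 18194 genes. Fixed gene lists, 31 in number, of cell types, responses and neighbouring tissues were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Standard errors are limma's moderated ones.

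The comparisons, gene lists, other settings and the rule for named genes were fixed before the data were examined. The rule took the 10 called genes with the largest rise and the 10 with the largest fall in each comparison, the 10 smallest p-values of the interaction, up to 4 members of each list with the smallest p, and the genes shared by the naive and MCAO genotype calls. Every gene of the first kinds is named. Of the list members eligible under the rule some were chosen for naming after their values were seen. Genes whose other probe sets differ in direction or call are named with that fact.

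The other settings fixed in this way were an intensity trend with a robust prior, leaving out dim genes, all probe sets or their mean, median centring, repeated quantile normalization, array weights, stricter thresholds, a replicate block, a Gapdh 3 prime minus 5 prime covariate, only the arrays compared, and leaving out each array. An actin 3 prime minus 5 prime covariate, fits without arrays that stand apart, unblocked fits to the arrays of the blocked ones and the correlation of the MCAO effects without each array were added after the data were seen.

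The pipeline was tested on simulated data in which 100 genes were changed 2-fold and 100 were changed 1.5-fold. It recovered 95% and 57% for MCAO in wild type, 89% and 61% in knockout mice, 73% and 22% for the interaction, 98% and 79% for genotype after MCAO, 84% and 45% after sham and 85% and 58% in naive mice. With 3 sham arrays per genotype, smaller changes in the sham groups and in the interaction were often missed. Between 5 and 13 unchanged genes were called per comparison. The simulated noise was normal and independent between arrays, with 1 spread per gene, so structure shared by arrays was not simulated.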

Results

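In wild type mice, 24 h after middle cerebral artery occlusion (MCAO), the ischemic hemisphere was compared with the sham hemisphere. Lcn2, which codes for an iron-binding acute-phase protein, rose by 5.61 on the log2 scale (SE 0.47, adjusted p = 1.39e-07, n = 7 and 3). The cytokine gene Il6 rose by 4.80 (SE 0.78, adjusted p = 0.000281) and the chemokine gene Cxcl2 by 4.31 (SE 0.82, adjusted p = 0.00118). The heat shock genes Hspb1 and Hspa1a rose by 4.16 (SE 0.21, adjusted p = 6.29e-11) and 4.15 (SE 0.41, adjusted p = 1.44e-06). Cd14 (4.71), Tgm1 (4.29), Timp1 (4.07), Ccl3 (3.89) and the neutrophil gene S100a8 (3.76, SE 0.58, adjusted p = 0.000176) completed the 10 largest rises.

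On the falling side in wild type P2ry12, a purinergic receptor of resting microglia, changed by -2.71 (SE 0.24, adjusted p = 3.31e-07) and Gpr34 by -2.39 (SE 0.24, adjusted p = 1.66e-06). Gpr6 changed by -2.71 (SE 0.58, adjusted p = 0.00322) and Pde10a, a phosphodiesterase of striatal medium spiny neurons, by -1.96 (SE 0.34, adjusted p = 0.00062). Ankrd63 (-2.36), Mme (-2.03), Rasgrp2 (-1.99), Kcnv1 (-1.84), Gm12371 (-1.79) and Gabrd (-1.72), which codes for a GABA-A receptor subunit, were also lower. A further probe set of Gabrd pointed the other way and was not called. Mme was not called with the replicate number as a block. Rasgrp2 was not called without wild type sham array 1 (-0.71, adjusted p = 0.0622) or array 2 (-0.24, adjusted p = 0.375), where a different probe set had the highest mean.

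All 24 measured genes of reactive astrocytes rose in wild type (camera adjusted p = 1.74e-32, and adjusted p = 0.0261 with an estimated correlation), among them Socs3 (2.84), Cd44 (3.72) and Osmr (3.01). Of the cytokines and chemokines 17 of 20 rose, with Ccl9 at 3.76 and Ccl12 at 3.15 (camera adjusted p = 2.85e-16; adjusted p = 0.0859 with an estimated correlation), and all 20 were higher when p was adjusted over the list alone. Matrix and tissue remodelling genes rose in 17 of 19 cases, Lgals3 by 3.75 and Tnc by 2.98 (camera adjusted p = 2.08e-14; adjusted p = 0.0967 with an estimated correlation). Apoptosis and DNA damage genes rose in 11 of 15 cases, Cdkn1a by 3.23 and Fas by 1.33 (camera adjusted p = 1.99e-10; adjusted p = 0.0261 with an estimated correlation). Oxidative stress genes rose in 9 of 15 cases, Hmox1 by 3.38, Mt2 by 1.75 and Srxn1 by 1.35 (camera adjusted p = 1.45e-10; adjusted p = 0.0261 with an estimated correlation).

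Complement and antigen presentation genes rose in 11 of 16 cases in wild type, H2-K1 by 1.23 (camera adjusted p = 7.23e-08; adjusted p = 0.0967 with an estimated correlation). Interferon response genes rose in 10 of 19 cases, Ifitm3 by 1.89 and Gbp2 by 1.80 (camera adjusted p = 7.05e-07; adjusted p = 0.192 with an estimated correlation). Markers of infiltrating monocytes and neutrophils rose in 6 of 22 cases, S100a9 by 3.61, and 11 were higher when adjusted over the list alone (camera adjusted p = 8.48e-06; adjusted p = 0.224 with an estimated correlation). Genes of endothelial activation were higher in 6 and lower in 1 of 12 cases, with Ch25h at 3.11 and Icam1 at 2.11 (camera adjusted p = 0.00066; adjusted p = 0.224 with an estimated correlation). Heat shock proteins were higher in 5 and lower in 1 of 18 cases (camera adjusted p = 0.0101; adjusted p = 0.498 with an estimated correlation). Immediate early genes split, with 10 higher and 4 lower of 23 (camera adjusted p = 0.125). Atf3 rose by 2.95, whereas Nr4a3 was at -1.39 on its chosen probe set, 2 other probe sets pointed the other way, and their mean of -0.28 was not called (adjusted p = 0.0586).

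Of 15 genes of striatal medium spiny neurons 11 were lower and none higher (camera adjusted p = 5.48e-08; adjusted p = 0.224 with an estimated correlation), and of 18 glutamatergic and pan-neuronal genes 9 were lower, Camkk2 by -1.04 and Gria2 by -0.88 (camera adjusted p = 5.48e-08; adjusted p = 0.0822 with an estimated correlation). Microglial markers were lower in 6 and higher in 2 of 17 cases, P2ry13 at -1.38 and Selplg at -1.12 (camera adjusted p = 0.000254; adjusted p = 0.224 with an estimated correlation). Adrenergic and cAMP signalling genes were lower in 7 and higher in 2 of 25 cases, with Akap5 at -1.61 and Prkar2b at -1.07 (camera adjusted p = 0.00515; adjusted p = 0.224 with an estimated correlation). Oligodendrocyte and myelin genes were higher in 7 of 16 cases, Cldn11 by 0.86 (camera adjusted p = 0.039; adjusted p = 0.55 with an estimated correlation), and the precursor gene Gpr17 was at -1.51. The vascular genes Vwf and Cdh5 rose by 1.10 and 1.49, and Gal by 1.83.

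Smaller shifts of whole lists were called in wild type for mitochondrial genes (0 of 18 members called, camera adjusted p = 0.0167, and adjusted p = 0.542 with an estimated correlation), resting astrocytes (1 higher and 2 lower of 15, camera adjusted p = 0.0137, and adjusted p = 0.401 with an estimated correlation), cholesterol synthesis (2 of 13 higher, camera adjusted p = 0.0277, and adjusted p = 0.55 with an estimated correlation) and cell division (2 of 18 higher, camera adjusted p = 0.039, and adjusted p = 0.424 with an estimated correlation). In this comparison camera called no shift for endothelial and blood-brain barrier genes (5 higher and 1 lower of 16), endoplasmic reticulum stress (4 higher of 15), hypoxia and glycolysis (3 higher and 2 lower of 15), oligodendrocyte precursors (2 higher and 1 lower of 9), GABAergic interneurons (1 lower of 13) or lymphocytes (0 of 14). Among markers of neighbouring tissue, meninges and fibroblasts had 4 higher and 1 lower of 14, beside 2898 of 18194 genes called in all. Thalamus and hypothalamus had 1 higher of 15. For choroid plexus 0 of 13 were called, for cerebellum and hindbrain 0 of 13 and for erythrocytes 0 of 6.

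In wild type limma called 2898 of 18194 genes, 1578 higher and 1320 lower after MCAO, of which 367 rose and 154 fell at least 2-fold. With each array centred on its median 37.4% of the called genes were higher and without dim genes 48%, against 54.5% as deposited. In wild type, at least 1 further probe set pointed the other way for Gabrd and Nr4a3. Not all further probe sets of the same direction passed for Pde10a, Cd44, Osmr, Gria2, H2-K1, Mme, Rasgrp2 and Cdh5. Leaving out wild type sham array 1, 2 or 3 left 1425, 1846 or 1667 genes.

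**Figure D1:**
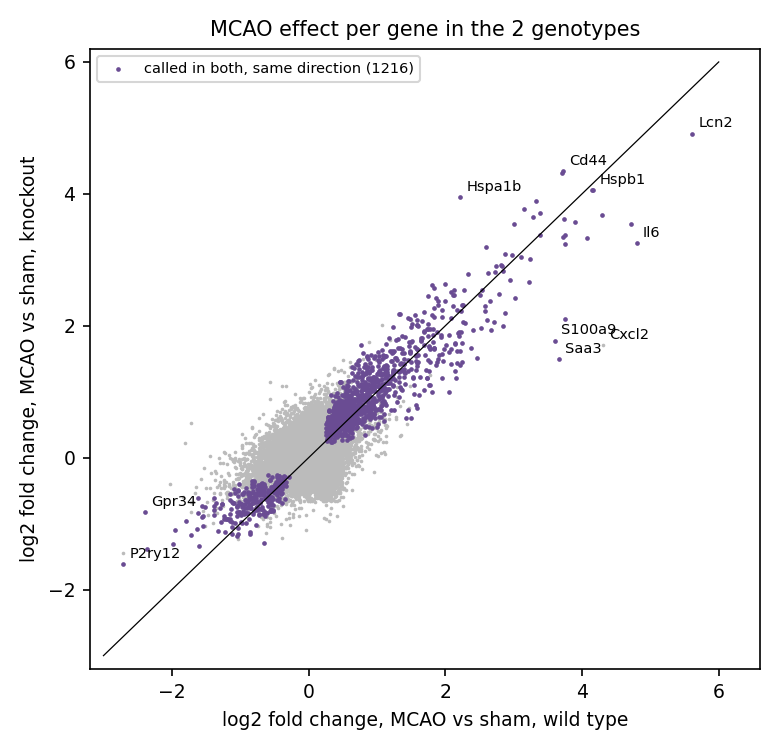
Log2 change after MCAO of each gene in wild type (horizontal) and knockout mice (vertical), from 7 MCAO and 3 sham arrays per genotype. Genes called in both in the same direction are coloured, and some genes are labelled. Lcn2 stands at 5.61 in wild type and 4.91 in knockout mice, and P2ry12 at -2.71 and -1.62. The interaction did not pass for Lcn2 (adjusted p = 0.472).

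In knockout mice Lcn2 rose after MCAO by 4.91 (SE 0.47, adjusted p = 7.68e-07, n = 7 and 3), Cd44, a hyaluronan receptor, by 4.35 (SE 0.29, adjusted p = 7.44e-09), and the heat shock genes Hspa1a, Hspb1 and Hspa1b by 4.06, 4.05 and 3.95. Emp1 (4.32), Cebpd (3.89), Ccl12 (3.78), Ifi202b (3.71) and Tgm1 (3.69) made up the rest of the 10 largest rises. Of 3 further Cd44 probe sets, 1 was called in the opposite direction, and the further probe sets of Emp1 and Cebpd pointed the other way without a call. P2ry12 again led the falls at -1.62 (SE 0.24, adjusted p = 8.1e-05).

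The other large falls in knockout mice were in Ankrd63 (-1.38, SE 0.36, adjusted p = 0.00839), Itpka (-1.34), Rasgrp2 (-1.32), Otof (-1.29), Fibcd1 (-1.23), Cacng3 (-1.18), Gabrd (-1.18), Slc22a8 (-1.16) and Plk5 (-1.16). Several of these rested on single sham arrays. Without knockout sham array 1, Ankrd63 had an adjusted p of 0.061 and Rasgrp2 of 0.44. Without array 2 or array 3, Fibcd1 had an adjusted p of 0.175 or 0.187, and Slc22a8 one of 0.104 in both cases.

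All 24 genes of reactive astrocytes rose in knockout mice as well (camera adjusted p = 2.04e-25; adjusted p = 0.0447 with an estimated correlation), Osmr by 3.54 and Socs3 by 2.84. Oxidative stress genes rose in 13 of 15 cases, Srxn1 by 1.44 and Hmox1 by 3.38 (camera adjusted p = 1.57e-11; adjusted p = 0.0412 with an estimated correlation), and apoptosis and DNA damage genes in 12 of 15, Cdkn1a by 2.67 and Pmaip1 by 1.72 (camera adjusted p = 7.98e-09; adjusted p = 0.0412 with an estimated correlation). Heat shock proteins rose in 11 of 18 cases (camera adjusted p = 1.91e-09; adjusted p = 0.172 with an estimated correlation). Hspa4 rose by 1.11 on its chosen probe set, but the mean of its probe sets was 0.32 (adjusted p = 0.262). Endoplasmic reticulum stress genes rose in 10 of 15 cases, Manf by 0.67 and Dnajb9 by 0.72 (camera adjusted p = 1.82e-05; adjusted p = 0.198 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 13 cases, Hsd17b7 by 0.87 and Cyp51 by 0.64 (camera adjusted p = 0.000846; adjusted p = 0.396 with an estimated correlation), and in 4 after median centring.

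Matrix genes rose in 15 of 19 cases in knockout mice (camera adjusted p = 2.65e-10; adjusted p = 0.216 with an estimated correlation), cytokines and chemokines in 12 of 20, Ccl3 by 3.57 (camera adjusted p = 2.97e-06; adjusted p = 0.32 with an estimated correlation), and interferon response genes in 14 of 19, Gbp2 by 2.62 and Irgm1 by 1.43 (camera adjusted p = 5.88e-06; adjusted p = 0.253 with an estimated correlation). Complement and antigen presentation genes rose in 9 of 16 cases (camera adjusted p = 9.2e-05; adjusted p = 0.257 with an estimated correlation). Genes of endothelial activation were higher in 4 of 12 cases (camera adjusted p = 0.00164; adjusted p = 0.32 with an estimated correlation). Endothelial and blood-brain barrier genes were higher in 6 of 16 (camera adjusted p = 0.032; adjusted p = 0.69 with an estimated correlation), and hypoxia and glycolysis genes higher in 5 and lower in 1 of 15 (camera adjusted p = 0.032; adjusted p = 0.438 with an estimated correlation). Lymphocyte markers were lower in 4 of 14 cases, Cd8a at -0.56 (camera adjusted p = 0.000334; adjusted p = 0.216 with an estimated correlation). Medium spiny neuron genes were lower in 2 of 15 cases (camera adjusted p = 0.00684; adjusted p = 0.69 with an estimated correlation) and pan-neuronal genes in 3 of 18, Camkk2 at -0.83 (camera adjusted p = 0.00253; adjusted p = 0.32 with an estimated correlation). Pde10a was at -1.09 (adjusted p = 0.0251) and, without knockout sham array 1, at -0.58 (adjusted p = 0.235). Gpr6 at -1.44 did not pass (adjusted p = 0.0738).

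Infiltrating cell markers split in knockout mice, 4 higher and 3 lower of 22 (camera adjusted p = 0.972). S100a8 rose by 2.10 (adjusted p = 0.0122), with an adjusted p of 0.0679 without knockout sham array 2, while Camp was at -0.46 and Ltf at -0.42, with adjusted p of 0.0831 and 0.147 without knockout sham array 3. Microglial markers split too, 5 higher and 6 lower of 17, with Selplg at -0.97 and Siglech at -0.75. Their median change was 0.12, but camera pointed down (adjusted p = 0.747), and the median was -0.04 after median centring. Among single genes, Cldn11 rose by 1.52, Pcna by 0.88, Crem by 0.96 and Adcy7 by 1.30. Mcm3 rose by 1.29, with 1 of 4 further probe sets called in the opposite direction. In this comparison camera called no shift for immediate early genes (8 higher and 3 lower of 23), adrenergic and cAMP signalling (6 higher and 1 lower of 25), oligodendrocytes and myelin (5 higher of 16), cell division (4 higher and 1 lower of 18), GABAergic interneurons (2 higher and 1 lower of 13), oligodendrocyte precursors (2 higher and 2 lower of 9), resting astrocytes (1 higher and 1 lower of 15) or mitochondrial genes (1 higher of 18). Markers of neighbouring tissue were higher in knockout mice for meninges and fibroblasts in 7 of 14 cases (camera adjusted p = 0.0685) and 5 after median centring, choroid plexus in 1 of 13 (camera adjusted p = 0.0643), thalamus and hypothalamus in 1 of 15 and erythrocytes in 1 of 6. Cerebellum and hindbrain genes were lower in 1 of 13.

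In knockout mice limma called 4546 genes, 2925 higher and 1621 lower, of which 460 rose and 25 fell at least 2-fold. Median centring turned the split to 28.8% higher, from 64.3%, and moved the median of all genes to -0.16. Leaving out dim genes gave 79.9% higher (2792 higher and 701 lower) and a median of 0.12. The fall of lymphocyte markers, Camp and Ltf was therefore not separated from a shift that varies with level. In knockout mice, at least 1 further probe set pointed the other way for Cd44, Emp1, Cebpd, Osmr, Cd8a, Hspa4 and Mcm3. Not all further probe sets of the same direction passed for Srxn1, Pde10a, Hsd17b7, Cyp51, Crem, Rasgrp2 and Gabrd. Without knockout sham array 3 or 2 the count was 2341 or 2439, and with the actin 3 prime minus 5 prime difference as a covariate, added after the data were seen, it was 2857. Knockout sham and MCAO arrays had mean actin differences of 1.66 (SD 0.083) and 1.01 (SD 0.52), with overlapping ranges. Their mean interquartile ranges were 3.38 and 3.67. In wild type sham and MCAO arrays the actin means were 0.929 and 0.870, and the interquartile ranges 3.69 and 3.53. These array differences were not separated from an effect of MCAO in knockout mice.

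Wild type and knockout mice shared 935 genes higher after MCAO, where independent lists would share 253.7, and 281 lower, where 117.6 were expected; 92 were called in opposite directions. The changes correlated across genes with r = 0.573 (Pearson) and 0.182 (Spearman).

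**Figure D2:**
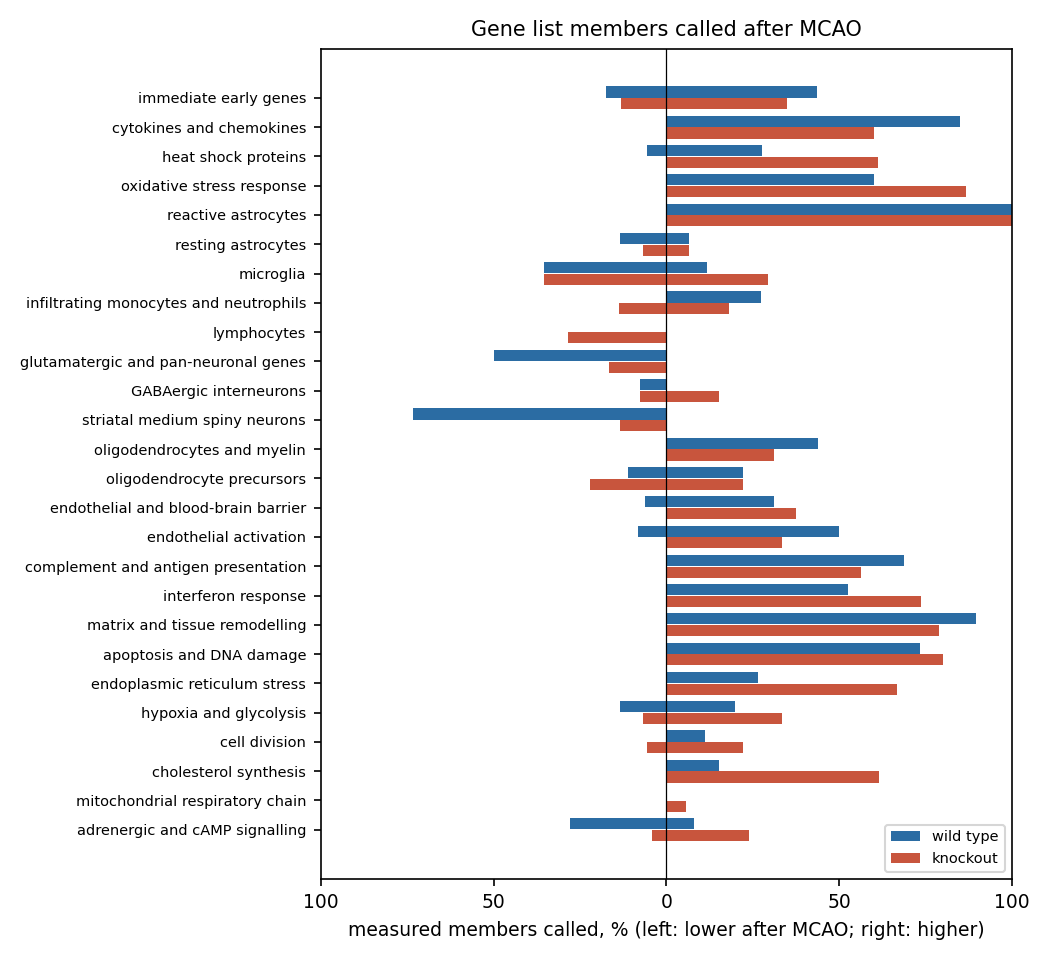
Percent of the measured members of each gene list called higher or lower after MCAO in wild type and in knockout mice. All 24 reactive astrocyte genes were higher in both, and medium spiny neuron genes were lower in 11 of 15 cases in wild type and 2 of 15 in knockout mice. The interaction did not pass for the medium spiny neuron list (camera adjusted p = 0.101; adjusted p = 0.922 with an estimated correlation).

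By the interaction test the change after MCAO was more positive in knockout mice for Hspa1b by 1.74 (SE 0.43, adjusted p = 0.0235, n = 7, 3, 7 and 3) and for the microglial gene Gpr34 by 1.57 (SE 0.34, adjusted p = 0.0182). It was smaller, or a stronger fall, for the acute-phase gene Saa3 by -2.17 (SE 0.51, adjusted p = 0.0198), the chemokine gene Cxcl1 by -1.17 (SE 0.29, adjusted p = 0.0243) and Nfkb2, a member of the NF-kappaB family, by -1.04 (SE 0.16, adjusted p = 0.0148). Without knockout sham array 3 limma called none of these genes and 0 in all, with 4251 at unadjusted p under 0.05. Hspa1b was also called lower in knockout mice between the sham groups, and such a difference enters the interaction with the opposite sign.

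The other largest positive differences were in Lrif1 (1.49), Abtb2 (1.46), Exph5 (1.46), Qtrt2 (1.43), Ano3 (1.37), C030023E24Rik (1.34), Grik3 (1.30) and the clock gene Per2 (1.30). On the negative side stood Boll (-1.30), E2f5 (-1.26), Tpx2 (-1.23), Aif1l (-1.18), Zg16 (-1.16), Prl2b1 (-1.09), Igf2bp1 (-1.09) and Psors1c2 (-1.08). A further probe set was called in the opposite direction for Grik3 and for E2f5, and the further probe sets of Abtb2 and Prl2b1 pointed the other way. The smallest p-values belonged to Hsf2bp (-0.88), Nfkb2, Sptlc3 (-0.75), Klk1b27 (-0.91), 8430426J06Rik (-0.80), Nkx2-5 (-0.88), 4933412E24Rik (-0.75), Ifna1 (-0.98), Actl9 (-0.80) and T2 (-0.96). For the interaction, at least 1 further probe set pointed the other way for E2f5, Tpx2, Grik3, Aif1l, Zg16, Prl2b1 and Abtb2. The test was not passed by every further probe set of Hspa1b, Qtrt2, Per2, Boll, Cxcl1, Hsf2bp, Nfkb2, Sptlc3, Sall1, Hsp90b1, Hspe1, Cd8a, Prkar2b, Akap5, Cxcl16, Ano3, Igf2bp1 and Actl9. All of these calls were absent without knockout sham array 3. Between the sham groups Lrif1 and Grik3 were also called lower in knockout mice, and Boll, E2f5, Aif1l, Zg16, Prl2b1 and Psors1c2 higher.

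By list, microglial genes were more positive in knockout mice in 5 of 17 cases, P2ry12 by 1.09, P2ry13 by 0.65 and Sall1 by 0.98 (camera adjusted p = 0.005; adjusted p = 0.721 with an estimated correlation). Endoplasmic reticulum stress genes were more positive in 4 of 15, Hsp90b1 by 0.75, Manf by 0.68, Creld2 by 0.68 and Dnajb9 by 0.59 (camera adjusted p = 0.0167; adjusted p = 0.721 with an estimated correlation). Heat shock proteins were more positive in 2 of 18, Hspe1 by 0.65 (camera adjusted p = 0.00131; adjusted p = 0.721 with an estimated correlation), and adrenergic and cAMP genes in 2 of 25, Prkar2b by 1.04 and Akap5 by 0.996 (camera adjusted p = 0.023; adjusted p = 0.721 with an estimated correlation). Infiltrating cell markers were more negative in 4 of 22, Camp at -0.56, Mpo at -0.93, Ltf at -0.56 and Elane at -0.62 (camera adjusted p = 0.00131; adjusted p = 0.721 with an estimated correlation). Lymphocyte markers were more negative in 1 of 14, Cd8a at -0.80, and in 10 when adjusted over the list alone (camera adjusted p = 0.000462; adjusted p = 0.721 with an estimated correlation). Cytokines were more negative in 2 of 20, Cxcl1 and Cxcl16 (-0.68; camera adjusted p = 0.023; adjusted p = 0.922 with an estimated correlation), and Fas stood at -1.01. Mitochondrial genes shifted up with 1 of 18 called (camera adjusted p = 0.0434; adjusted p = 0.922 with an estimated correlation), and their median changed sign after quantile normalization. None of the single-gene calls held without knockout sham array 3. Hsp90b1 was also called lower in knockout mice between the sham groups, and Mpo, Cd8a and Fas higher.

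The interaction test called 1744 genes, 744 more positive and 1000 more negative in knockout mice. Quantile normalization left 22.1% of 339 called genes more positive and median centring 24.5%, against 42.7% as deposited. Without dim genes it went the other way, with 522 more positive and 194 more negative (72.9%). Of the 1744 genes 854 were also called between the sham groups, all with the opposite sign, and only 2 between the MCAO groups; the interaction and the sham comparison share arrays and so share chance values. Calls with a more negative change had a median level of 5.53, the others one of 9.03. The more negative change of lymphocyte and infiltrating cell markers was therefore not separated from a shift that varies with level. Beside the fall to 0, the count was 165 without knockout sham array 2, 100 and 342 without wild type sham arrays 1 and 2, 2698 without knockout MCAO array 1, and 8 with the actin covariate.

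After MCAO limma called 8 genes between the genotypes, with 3165 of 18194 at unadjusted p under 0.05. Pmaip1, which codes for the pro-apoptotic protein Noxa, was lower in knockout mice by -1.47 (SE 0.20, adjusted p = 0.00223, n = 7 and 7), 1500015A07Rik by -1.09 (SE 0.09, adjusted p = 6.56e-07) and the cytokine gene Il18 by -0.47 (SE 0.07, adjusted p = 0.0118). Tmem243 (-0.63, adjusted p = 0.04) and 4930503L19Rik (-0.56, adjusted p = 0.0252) were lower too. Ring1, a Polycomb gene (0.70, adjusted p = 0.0252), Dusp6, a phosphatase that acts on ERK (0.70, adjusted p = 0.0252), and Ppp2r1b (0.50, adjusted p = 0.0398) were higher. Without knockout MCAO array 2 the adjusted p was 0.0943 for Ring1, Dusp6 and 4930503L19Rik and 0.124 for Tmem243 and Ppp2r1b. These 5 genes were also lost without knockout MCAO array 5 (4930503L19Rik at an adjusted p of 0.0829) and without wild type MCAO array 5 (0.0666) or 7 (0.0766), and at least 1 of them without knockout array 3 or 4 or any other wild type array. With the replicate number as a block Ring1, Dusp6, Ppp2r1b, Tmem243 and Il18 were not called (adjusted p = 0.0561, 0.0511, 0.0845, 0.0996 and 0.0504), whereas Pmaip1 and 1500015A07Rik were called in every setting.

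Not called between the MCAO groups were S100a9 at -2.09 (SE 0.47, adjusted p = 0.104), S100a8 at -1.75 (adjusted p = 0.117), Cxcl2 at -1.78 (adjusted p = 0.179), Lcn2 at -1.25 (adjusted p = 0.129), H2-K1 at -0.87 (adjusted p = 0.0664) and H2-D1 at -0.84 (adjusted p = 0.1). The microglial genes Gpr34 (0.76, adjusted p = 0.114), P2ry12 (0.68, adjusted p = 0.122) and P2ry13 (0.38, adjusted p = 0.12) were not called either. S100a9 and Lcn2 were lowest on knockout MCAO arrays 7, 2 and 5, with Lcn2 at 7.92, 8.37 and 8.48 and S100a9 at 5.50, 6.15 and 5.81. Arrays 2 and 5 had Gapdh 3 prime minus 5 prime differences of 0.383 and 1.18, array 7 one of -0.251. Without arrays 2 and 5, S100a9 was at -1.61 (adjusted p = 0.363) and S100a8 at -1.30 (adjusted p = 0.398). With the Gapdh covariate they were at -1.74 (adjusted p = 0.333) and -1.42 (adjusted p = 0.34). Both passed with the planned replicate block, for which the adjusted p-values are given under the processing. With the actin covariate, added after the data were seen, S100a9 (adjusted p = 0.0188), S100a8 (0.0291), Lcn2 (0.028), H2-K1 (0.0111), H2-D1 (0.0179), Gpr34 (0.0181), P2ry12 (0.0199) and P2ry13 (0.0216) passed. H2-K1 also passed without knockout MCAO array 1, 6 or 7 (adjusted p = 0.0427, 0.0282 and 0.0268) and H2-D1 without array 7 (adjusted p = 0.0493).

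As lists, infiltrating cell markers shifted down after MCAO in knockout mice (0 of 22 members called, camera adjusted p = 0.00183, and adjusted p = 0.859 with an estimated correlation), as did oligodendrocyte genes (0 of 16, camera adjusted p = 0.003, and adjusted p = 0.859 with an estimated correlation), lymphocyte markers (0 of 14, camera adjusted p = 0.0218, and adjusted p = 0.859 with an estimated correlation) and cytokines (0 of 20, camera adjusted p = 0.0254, and adjusted p = 0.962 with an estimated correlation). Microglial genes shifted up (0 of 17 called, 4 when adjusted over the list alone, camera adjusted p = 0.0167, and adjusted p = 0.859 with an estimated correlation), with adrenergic genes (0 of 25, camera adjusted p = 0.0218, and adjusted p = 0.859 with an estimated correlation) and heat shock proteins (0 of 18, camera adjusted p = 0.0471, and adjusted p = 0.962 with an estimated correlation). The single-gene counts of 0 came from limma, with 3165 of all genes at unadjusted p under 0.05.

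Between the MCAO groups limma called 8 genes, 3 higher and 5 lower. Median centring gave 25% higher and quantile normalization 54.5%, against 37.5%. Between the MCAO groups, at least 1 further probe set pointed the other way for Tmem243. The test was not passed by every further probe set of 4930503L19Rik. The count rose to 38 without knockout MCAO array 7 and to 986 with the actin covariate, or 245 when it was fitted to the MCAO arrays alone, and fell to 3 without knockout MCAO array 2 or 5 or wild type MCAO array 5 or 7. It was 13 and 16 without knockout arrays 1 and 6, and 4 without knockout array 4 or wild type array 6.

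After sham surgery Boll was higher in knockout mice by 1.34 (SE 0.20, adjusted p = 0.00838, n = 3 and 3) and Nrip2 by 0.98 (SE 0.15, adjusted p = 0.00838). Hspa1b was lower by -1.62 (SE 0.36, adjusted p = 0.0224), Pmaip1 by -1.498 (SE 0.30, adjusted p = 0.0183) and Aif1, a macrophage and microglia marker, by -0.83 (SE 0.16, adjusted p = 0.0164). The knockout sham arrays also had a larger actin 3 prime minus 5 prime difference, 1.66 (SD 0.083), than the wild type sham arrays, 0.929 (SD 0.077), and a narrower spread of values, with an interquartile range of 3.38 against 3.69. Without knockout sham array 3 or without wild type sham array 2 limma called none of these genes and 0 in all, with 3076 and 3569 at unadjusted p under 0.05.

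The remaining largest positive sham differences were in E2f5 (1.24), 2900052N01Rik (1.21), Aif1l (1.19), Prl2b1 (1.07), H2-Bl (1.05), Zg16 (1.04), Psors1c2 (0.999) and Ppp1r13l (0.95). The negative ones were in AI506816 (-1.26), Lrif1 (-1.22), Pnrc2 (-1.07), Slc25a16 (-1.03), Grik3 (-1.01), Gca (-0.96), H2-K1 (-0.96) and Gm16740 (-0.93). Lymphocyte markers were higher in 1 of 14 cases, Cd8a by 0.72, and in 8 when adjusted over the list alone (camera adjusted p = 0.00184; adjusted p = 0.792 with an estimated correlation), and infiltrating cell markers in 1 of 22, Mpo by 0.86 (camera adjusted p = 0.0435; adjusted p = 0.792 with an estimated correlation). Heat shock proteins were lower in 2 of 18 (camera adjusted p = 0.00482; adjusted p = 0.792 with an estimated correlation), endoplasmic reticulum stress genes in 1 of 15, Hsp90b1 at -0.54 (camera adjusted p = 0.0185; adjusted p = 0.792 with an estimated correlation), mitochondrial genes in 1 of 18 (camera adjusted p = 0.0272; adjusted p = 0.792 with an estimated correlation) and microglial genes in 1 of 17 (camera adjusted p = 0.0442; adjusted p = 0.792 with an estimated correlation). Fas was higher by 0.79 and Cldn11 at -0.72. These single-gene calls were likewise absent without knockout sham array 3 or wild type sham array 2.

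The sham comparison called 1101 genes, 641 higher and 460 lower in knockout mice. Quantile normalization left 303 genes, 85.5% of them higher against 58.2% as deposited. Without dim genes the direction turned, with 129 higher and 353 lower (26.8%), and 6 genes were called with the actin covariate. Genes higher in knockout mice had a median level of 5.53 and lower ones of 9.41. The rise of lymphocyte and infiltrating cell markers was therefore not separated from a shift that varies with level. Between the sham groups, at least 1 further probe set pointed the other way for E2f5, Aif1l, Prl2b1, Pnrc2, H2-K1, Zg16 and Grik3. Further probe sets of the same direction did not all pass for Boll, Nrip2, Ppp1r13l, Hspa1b, Gca, Cd8a, Hsp90b1 and 2900052N01Rik. The count was 17 without knockout sham array 2, and 120 and 103 without wild type sham arrays 1 and 3.

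In naive hemispheres, Fgf1, a fibroblast growth factor gene, was higher in knockout mice by 2.67 (SE 0.12, adjusted p = 3.38e-09, n = 7 and 8), the protocadherin gene Pcdhb9 by 2.12 (SE 0.19, adjusted p = 1.46e-05) and Fxyd2, a regulator of the sodium pump, by 1.74 (SE 0.08, adjusted p = 3.38e-09). Pmaip1 was lower by -2.33 (SE 0.23, adjusted p = 2.94e-05), Lcn2 by -1.51 (SE 0.36, adjusted p = 0.0106), S100a8 by -1.47 (SE 0.23, adjusted p = 0.00067) and S100a9 by -1.42 (SE 0.20, adjusted p = 0.000331). No pair of a wild type and a knockout naive array held an exactly equal value (0 of 56 pairs), whereas all 28 wild type pairs and all 21 knockout pairs did. All 100 surgery pairs of different genotype held such values as well. A separate normalization run for each naive genotype is inferred from this, so that genotype and run coincide in every naive result. The knockout pairs held 1744 to 2878 equal values each, the wild type pairs 1 to 48, and the reason was not tested. Fgf1 and Pcdhb9 did not pass between the sham groups, at -0.11 (adjusted p = 0.926) and -0.64 (adjusted p = 0.607). Neither gene passed between the MCAO groups (adjusted p = 0.19 and 0.175). Pcdhb9 lay at 8.16 to 8.22 on the wild type sham arrays and at 7.54 to 7.56 on the knockout sham arrays, without overlap. The sham p-value rests on a spread over all surgery arrays, which include wild type MCAO arrays at 4.0 to 8.1 in Pcdhb9. It therefore could not decide whether the sham groups differ in Pcdhb9. Of the wild type MCAO arrays, 1 to 3 had lower Fgf1, 6.61 to 6.82, than 4 to 7, 8.88 to 9.44. Lcn2 was not called after quantile normalization (adjusted p = 0.0631). It lay at 6.65 to 6.97 on wild type arrays 1 to 4, 4.82 to 4.99 on arrays 5 to 8 and 4.20 to 4.49 on the knockout arrays.

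Serpina9 (1.85), Garem1 (1.67), Dmxl1 (1.58), Snhg12 (1.501), Notch4 (1.35), Hccs (1.15) and Tnfrsf25 (1.05) were the other large rises in naive knockout mice; 1 further probe set of Notch4 was called in the opposite direction. G530011O06Rik (-2.10), 4831440E17Rik (-1.59), Ch25h (-1.43), Tcf23 (-1.34), 1500015A07Rik (-1.26) and Plin4 (-1.21) were the other large falls. Plin4 lay at 8.02 to 8.29 on wild type arrays 1 to 4, 6.71 to 7.42 on arrays 5 to 8 and 6.12 to 6.52 on the knockout arrays. Among list members Tgm1 (-0.93), Timp1 (-0.60), Fas (-0.44), Ccl12 (-0.43) and Cxcl2 (-0.46) were lower, and Ccl7 (0.38), Vegfa (0.53), Sqle (0.39), Mcm2 (0.51) and Ifit3 (0.42) higher. Ccl12 and Cxcl2 were not called after quantile normalization (adjusted p = 0.0944 and 0.185), nor Ccl7 and Ifit3 after median centring (adjusted p = 0.206 and 0.083).

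Infiltrating cell markers were lower in 9 and higher in 2 of 22 cases in naive knockout mice, Mmp8 at -0.67 (camera adjusted p = 0.00296; adjusted p = 0.592 with an estimated correlation), and lymphocyte markers lower in 5 of 14, Cd3g at -0.69 (camera adjusted p = 0.00443; adjusted p = 0.592 with an estimated correlation). Among all naive calls, genes lower in knockout mice had a median level of 4.84 and higher ones of 8.35. A fall of these markers was therefore not separated from a shift that varies with level. Microglial genes were higher in 4 of 17 cases, Siglech by 0.60, P2ry13 by 0.46 and Cx3cr1 by 0.57 (camera adjusted p = 0.0403; adjusted p = 0.45 with an estimated correlation). Endothelial and blood-brain barrier genes were higher in 2 of 16, Kdr by 0.48 (camera adjusted p = 0.0448; adjusted p = 0.399 with an estimated correlation), and meningeal genes in 2 of 14, Col1a1 by 0.61 (camera adjusted p = 0.0221; adjusted p = 0.45 with an estimated correlation). Of the endothelial activation genes 4 of 12 were lower, among them Sele (-0.43) and Selp (-0.50; camera adjusted p = 0.0543). P2ry13, Cx3cr1 and Kdr were not called after median centring (adjusted p = 0.0818, 0.106 and 0.0998). Cx3cr1 was also lost without knockout naive array 2 (adjusted p = 0.0753), and Selp without knockout naive array 7 (adjusted p = 0.0994).

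Between the naive groups, at least 1 further probe set pointed the other way for Notch4. Further probe sets of the same direction did not all pass for Fxyd2, Vegfa, Col1a1, Cx3cr1 and Selp. In naive mice limma called 2669 genes, 1158 higher and 1511 lower. Without wild type naive array 6, which correlated with its group at a mean r of 0.817, the count was 6627, 4375 higher and 2252 lower, and cholesterol synthesis genes were higher in 11 of 13 cases (camera adjusted p = 0.00183; adjusted p = 0.608 with an estimated correlation), 3 of them after median centring. In that fit endothelial activation genes were lower in 5 and higher in 2 of 12 cases (camera adjusted p = 0.0136; adjusted p = 0.24 with an estimated correlation), and mitochondrial genes were lower in 1 of 18 (camera adjusted p = 0.0136; adjusted p = 0.813 with an estimated correlation). Median centring left 7.32% of calls higher, against 43.4%, and moved the median of all genes to -0.14 in the full set; without that array the share went from 66% to 19%. Leaving out dim genes moved it up instead, to 95.8% in the full set (410 higher and 18 lower) and 94.6% without that array.

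Pmaip1, 1500015A07Rik, 4930503L19Rik and Il18 were lower in knockout mice both naive and after MCAO. Of independent lists 0.415 shared lower genes were expected, and no gene was shared on the higher side. Pmaip1, 1500015A07Rik and 4930503L19Rik lie on chromosome 18, the chromosome of the targeted locus, which held 2.55% of the genes tested. Over all genes the naive and MCAO genotype changes correlated at r = 0.301, naive and sham at -0.136 and sham and MCAO at -0.25. Without wild type naive array 6 the naive and MCAO value was 0.272, where other splits of the MCAO arrays gave -0.252 to 0.273. Naive and sham calls shared 37 higher genes, where 40.8 were expected, and 6 lower, where 38.2 were expected, while 88 had opposite directions. In naive mice 4930503L19Rik was at -0.91 (adjusted p = 0.000144) and Il18 at -0.58 (adjusted p = 0.0428), a call that Il18 lost without knockout naive array 2 (adjusted p = 0.083) and in most other such fits. Wild type naive array 6 held the highest Il18 value, 11.70, beside 10.14 to 10.67 on the other wild type arrays and 9.84 to 10.14 on the knockout arrays. After sham surgery Pmaip1, 1500015A07Rik (-0.89, adjusted p = 0.00838) and Il18 (-0.58, adjusted p = 0.016) were lower and 4930503L19Rik was at -0.26 (adjusted p = 0.256). Without wild type naive array 6 the shared genes were 7 of the 8, adding Ring1, Tmem243 and Ppp2r1b, where 1.34 were expected.

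**Figure D3:**
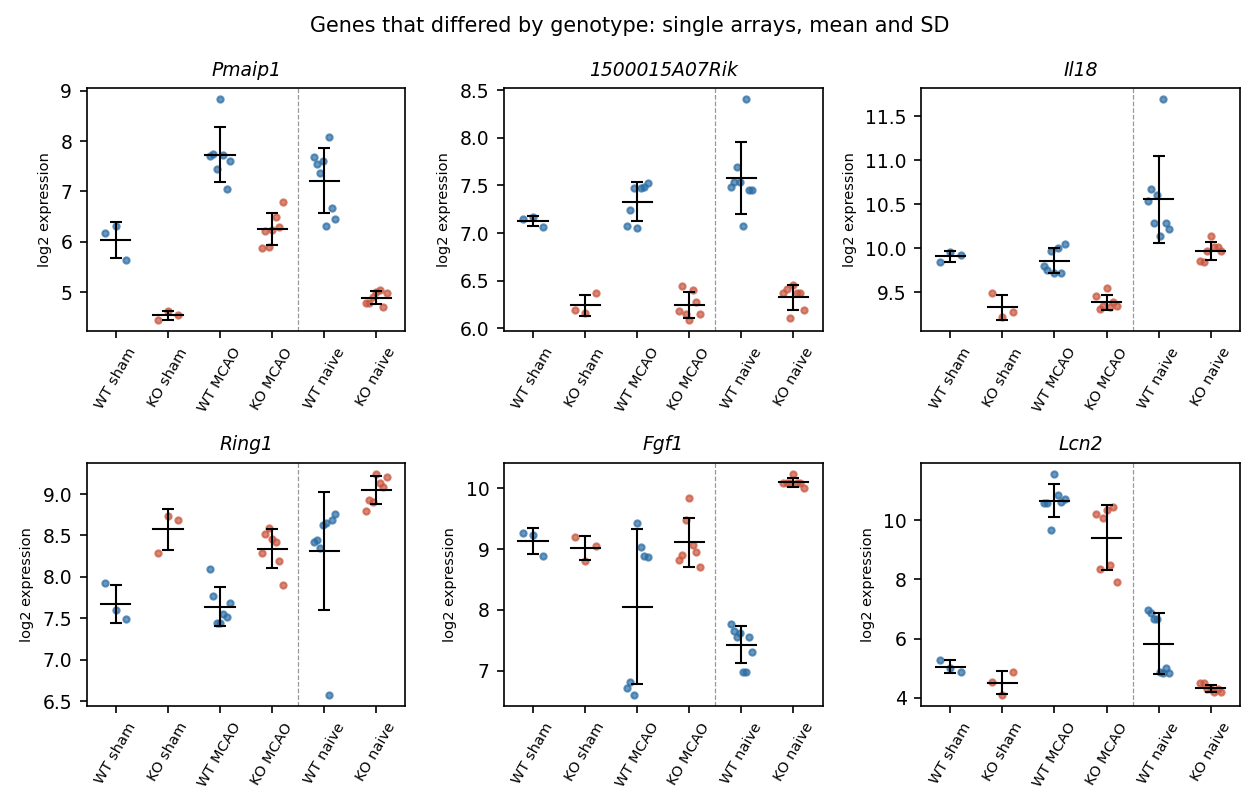
Log2 level of Pmaip1, 1500015A07Rik, Il18, Ring1, Fgf1 and Lcn2 on each array of the 6 groups, with mean and SD. Pmaip1 was lower in knockout mice by -1.498 after sham, -1.47 after MCAO and -2.33 in naive mice.

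**Figure D4:**
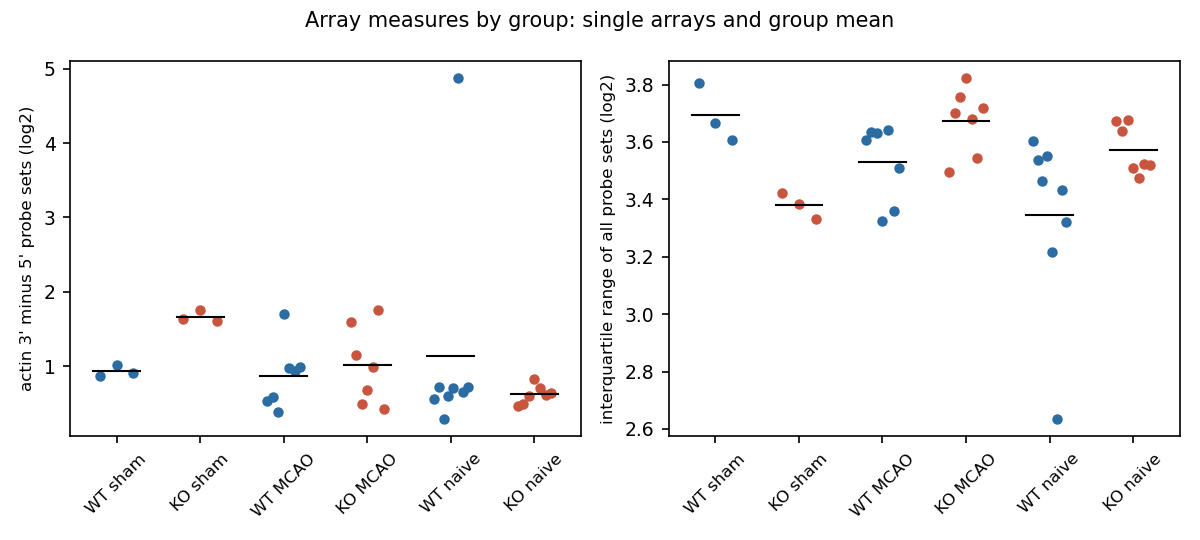
Actin 3 prime minus 5 prime difference (log2) and interquartile range (log2) of each array by group. The knockout sham arrays lie at 1.60 to 1.76 in actin difference and the wild type sham arrays at 0.86 to 1.01.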

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

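The tests of explanations and the splits of arrays described in this part were chosen after the results were seen. Among 20 array measures and 282 pairs of a named gene and a group tested for a value standing apart from its group, about 1 in 20 would do so by chance; 38 pairs, in 35 genes, did. Wild type naive array 6 stood apart in its mean correlation (gap ratio 0.94), interquartile range (0.602), Gapdh 3 prime minus 5 prime difference (0.971) and actin difference (0.904), and in 12 named genes, among them Ch25h, Kdr and Pcdhb9. Knockout naive array 4 stood apart in mean correlation (0.71) and Gapdh difference (0.633) and in 2 genes, Fgf1 and Sqle. Wild type MCAO array 4 stood apart in mean correlation (0.65) and in 12 genes, among them Cxcl2 and S100a9 on the high side and Ccl12 and Osmr on the low side. Knockout MCAO array 7 stood apart in 7 genes, among them Cd44 and Srxn1. Single genes stood apart on knockout MCAO array 1 (1, Ltf), knockout MCAO array 4 (1, Fas), knockout naive array 2 (1, Siglech), knockout naive array 5 (1, Cd3g) and wild type MCAO array 7 (1, Prl2b1). The response to MCAO differed between genotypes for 1744 genes, which rested on single sham arrays.

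Other splits of the same arrays tested whether chance could be excluded. It could for MCAO in wild type, where 1 of 100 splits called as many genes (2898 against at most 1662 in the others). Chance could also be excluded for MCAO in knockout mice (1 of 100, 4546 against 860). The same held for the genes shared by both MCAO responses (1 of 100, 1216 against 240). The naive genotypes stood apart as well (1 of 100, 2669 against 0, and without wild type naive array 6 1 of 100, 6627 against 1688). The inferred separate normalization runs would set the real naive split apart without a genotype effect, so these splits could not decide on genotype. The MCAO genotypes with the actin covariate gave 986 genes against 6 (1 of 100). That covariate was added after the data were seen, and the splits do not allow for its choice, so they could not exclude chance. Chance was not taken as excluded for the interaction (2 of 100) or for the calls shared by naive and MCAO genotypes (2 of 100). In each another split gave more, 1768 against 1744 and 5 against 4. The interaction also fell to 0 of limma's calls without knockout sham array 3 (4251 at unadjusted p under 0.05). Between the MCAO genotypes 2 of 100 splits called as many, but another split called 210 genes against the real 8. The count of calls therefore could not exclude chance, and it does not weigh the 8 genes singly. The 210 genes point to a structure of the samples. With the actin covariate the same splits, the one with 210 genes among them, called at most 6 genes. What else the arrays of that split share was not tested.

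Genes differed between the naive genotypes, such as Fgf1 and Pmaip1. A separate normalization run for each naive genotype could not be told apart from genotype: 68.7% of the calls without wild type naive array 6 had the same sign in the jointly normalized MCAO arrays, where other splits reached 71.51%. Without that array 7 of the 8 MCAO genotype calls were also called naive in the same direction, where independent lists would share 1.34. This overlap was not set against other splits of the arrays. With all naive arrays another split gave 5 shared calls against the real 4. The overlap therefore could not decide whether the run was the whole cause. The low-quality wild type array as the whole cause is argued against by the 6627 genes called without it. A genotype difference may remain for the shared genes, Pmaip1 among them, as a hypothesis. For Pmaip1, 1500015A07Rik and 4930503L19Rik an effect of the receptor was not told apart from a strain segment on chromosome 18, taken up below.

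Genes differed between the sham genotypes, such as Boll and Hspa1b, and 10 splits are too few for a share under 0.05 (1 of 10, real value 1101, highest other 40). The state of the RNA could account for part: across called genes the slope on the actin difference within MCAO groups correlated with the sham change at r = 0.7785 (permutation p = 0.0428), but it predicted a median change of 0.11 of the 0.553 seen. With the actin covariate 6 genes were called, as the median change went from 0.553 to 0.436 and the median SE from 0.139 to 0.145. A narrower spread on the knockout sham arrays stayed open as well, with 303 genes left after quantile normalization and a median change of 0.43. A genotype difference present in every state was not decided by the 22.8% of calls with the same sign after MCAO, since other splits gave 7.90% to 93.01%.

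Genotype differences after MCAO and in naive mice included genes of chromosome 18, such as Pmaip1, 1500015A07Rik and 4930503L19Rik. A strain segment kept around the targeted locus is a candidate explanation: 7 of the 100 smallest p-values after MCAO lay on chromosome 18, where 2.55 were expected, but 5 of 100 splits gave as many. In naive mice without wild type array 6 there were 10, which 2 of 100 splits reached, but chromosomes X and 5 held 11 each, where 3.42 and 6.22 were expected. Within 100 tested genes of the locus lay 5 of the 7, where 3.05 were expected, and 5 of the 10, where 4.36 were expected. Strain variants under single probe sets stayed open too, since 4 of the 7 genes with further probe sets, Fgf1 among them, had another probe set of the same sign at unadjusted p under 0.05. Pmaip1 and 1500015A07Rik had 0 further probe sets, so this could not be checked for them.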

How the results depend on the processing

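Fits with the actin covariate, fits without arrays that stand apart, unblocked fits to the arrays of the blocked ones and the correlation of the MCAO effects without each array were added after the data were seen; the others were planned. Results are named in the order MCAO in wild type, MCAO in knockout mice, interaction, genotype after MCAO, after sham and naive, with 2898, 4546, 1744, 8, 1101 and 2669 genes. The cause of the movements was not tested. Of 6116 values of 230 named gene results, 5318 were the same, 782 weaker, 15 stronger and 1 reversed; 119 gene results were the same throughout. The reversed one was E2f5 in the interaction, 0.85 (adjusted p = 0.0284) with all probe sets tested separately.

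Array quality weights gave 4472, 7239, 4098, 12, 5891 and 7637 genes, 9 shared genotype calls instead of 4, 2118 shared MCAO calls instead of 1216, and r = 0.631. An adjusted p under 0.01 gave 1286, 2171, 0, 2, 6 and 1342 genes and 2 shared genotype calls; the 0 of limma stood beside 5732 at unadjusted p under 0.05. A change of at least 1.5-fold gave 1513, 1600, 5 after MCAO, 432 after sham and 340 naive. Leaving out dim genes gave 716 in the interaction, 482 after sham, 428 naive, 1 shared call and r = 0.721. Quantile normalization gave 339, 303 after sham, 1500 naive and r = 0.689; median centring gave 565 after sham. All probe sets gave 22 after MCAO, 4940 naive and 16 shared calls, and the mean of probe sets r = 0.604. The Gapdh covariate gave 757 in the interaction, 2 after MCAO and 6680 naive, and only the arrays compared 3 after MCAO and 3402 after sham.

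The replicate numbers were not taken to pair the arrays, although so few pairs could not rule out a pairing. Between arrays of equal number r ran from -0.278 to 0.205 for the sham genotypes and from -0.204 to 0.336 for the MCAO genotypes. Between the naive genotypes it ran from -0.092 to 0.361, with 5 of 7 pairs over 0.1, where the rule asked for every pair. With the number as a block the counts were 2116, 3808, 2, 8, 2402 and 1868, of which 1716, 3229, 0, 3, 1061 and 1814 were among the genes called as deposited. On the same arrays with no block they were 2260, 4274, 2, 8, 3178 and 2414. With the block Mme in wild type MCAO had an adjusted p of 0.0526, and S100a8 and S100a9 passed between the MCAO genotypes (adjusted p = 0.0481 and 0.0242).

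The actin covariate gave 2857 for MCAO in knockout mice, 8 in the interaction, 986 after MCAO (245 on the MCAO arrays alone, 240 of them among the 986), 6 after sham and 6243 naive. Without knockout MCAO arrays 2 and 5 there were 449 in the interaction and 2 after MCAO, and without wild type and knockout MCAO arrays 4 2183 after sham. Without wild type naive array 6 there were 6627 naive genes and 7 shared calls, and with it left out 4048 after quantile normalization, 6221 after centring, 6611 with a trend and 3380 without dim genes. Leaving out single arrays gave 1425 to 2919, 2341 to 4944, 0 to 2698, 3 to 38, 0 to 1116 and 2004 to 6627 genes, and r from 0.523 to 0.614. The lowest counts came without wild type sham array 1 for MCAO in wild type, knockout sham array 3 for MCAO in knockout mice and the interaction, knockout sham array 3 or wild type sham array 2 after sham, knockout MCAO array 2 or 5 or wild type MCAO array 5 or 7 after MCAO, and knockout naive array 3. Limma's 0 stood beside 4251 genes at unadjusted p under 0.05 in the interaction and 3076 and 3569 after sham. With an estimated correlation camera called 3, 3, 0, 0, 0 and 0 lists instead of 19, 16, 8, 7, 6 and 5.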

Other observations

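In naive mice S100a9 lay at 6.66 to 7.39 on wild type arrays 1 to 4, at 6.05 to 6.61 on arrays 5, 7 and 8, at 7.50 on array 6 and at 5.32 to 5.59 on the knockout arrays. Pmaip1 lay at 7.37 to 7.68 on wild type arrays 1 to 4, 6.32 to 6.67 on arrays 5, 7 and 8, 8.09 on array 6 and 4.70 to 5.04 on the knockout arrays. By the inferred separate runs, genotype and normalization run coincide in these values.

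Fgf1 split the wild type MCAO arrays: arrays 1 to 3 lay at 6.61 to 6.82 and arrays 4 to 7 at 8.88 to 9.44, beside 8.89 to 9.27 in wild type sham arrays. Pcdhb9 split in the same place, 3.99 to 5.50 against 6.77 to 8.11. In naive mice Fgf1 lay at 6.98 to 7.76 in wild type and 10.00 to 10.24 in knockout mice. S100a8 was lowest in knockout MCAO arrays 7, 5 and 2, at 5.61, 6.12 and 6.46, where the others lay at 8.03 to 9.09. Arrays 5 and 2 had the highest Gapdh 3 prime minus 5 prime differences of this group, 1.18 and 0.383, and array 7 the lowest, -0.251. No explanation was tested for these values.

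Of the 100 smallest p-values between the MCAO genotypes, 11 belonged to genes of chromosome 17, where 4.62 were expected; Ring1, H2-K1 and H2-D1 were among them. Chromosome 5 also held 11, where 6.22 were expected. These chromosomes were singled out after their values were seen, and no other splits were counted for them.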
